A study of Homo sapiens with 16 samples.

How the data were processed

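Total RNA of 4 glioblastoma lines and of normal glial cells (FGG) was hybridised in pairs on 16 2-colour arrays. Per the labels, the RNA was labelled with Cy3 or Cy5 using an Agilent linear amplification kit, every array held 1 tumour line and FGG, and each line had 2 arrays in each dye orientation. Cells were grown in the same serum-supplemented medium, per the labels' protocols. Samples were grouped by the tumour line that the titles name and numbered by the slide number in the titles.

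The deposited table holds 1 log ratio per probe and array, read here as log2. The authors' image analysis, background correction, normalization and log base are not given in the sources used here, and no intensities were used, so dim and saturated probes could not be set aside. The array means lay within 0.00641 of 0. The medians in replicate order were 0.0455, 0.0344, -0.00826 and 0.00250 for A172, and -0.00268, 0.0422, 0.000129 and 0.0396 for T98G. They were 0.0138, 0.0335, -0.00498 and 0.0490 for U118, and 0.00330, 0.0511, -0.0369 and 0.0531 for U87. Each value sets 1 channel against the other, and with array means this close to 0 a shift of all transcripts in 1 direction would not be seen.

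Scale and direction were examined from the values. Base 10 was excluded by the range. Natural logs were not, and that reading was run as an alternative. The mean was above 0 on all 8 arrays with the tumour line in Cy5 and below 0 on all 8 with it in Cy3. The former carry 9 decimals and the latter 6 significant digits, so 1 of these sets may have been turned before deposit. Whether a set was turned, and which, stays unknown, and with it the direction of the ratio. Arrays needed no change of sign here. The number of arrays limits the precision.

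The plan, fixed before the data were examined, was to average probes by gene and to test 32 gene lists. No table used here pairs the probe identifiers with genes: 0 of 38425 matched an identifier, symbol or accession of the GRCh38.p14 gene table. Tests were therefore run on probes, the lists were not tested, and a planned check of the ratio's direction on genes often deleted in glioblastoma could not be made. At most 2 positive and 2 negative probes are named, chosen as the extremes of the average over lines among called probes with the same sign on all 16 arrays.

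Models were fitted with limma 3.58.1 in R 4.3.3. Values were used as deposited. One linear model over all 16 arrays had a coefficient for each line and a dye covariate (lmFit and eBayes, 11 residual degrees of freedom), and gave each line against FGG and each pair of lines. The comparison of tumour lines with FGG was an intercept on the 4 line means, and that of the more with the less aggressive lines a difference of 2 against 2 line means, with limma in both. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes and a mean log ratio of at least 1 in size. Shared calls were set against the product of the list lengths and against 20 simulations of unchanged lines, in which noise with the real spread between arrays was joined by 1 deviation of FGG, drawn per probe with the SD between the 4 line means. That size is an assumption, chosen after the data were seen. The dye term was past an adjusted p of 0.05 for 8438 probes, of which 63 differed at least 2-fold between orientations.

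Runs of identifiers were defined after the data were seen, by a new run wherever 2 successive identifiers differed by more than 200. A run's value on an array is the mean of its probes. Limits of 100, 150 and 300 gave 1959, 1699 and 1446 runs.

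The fits were tested on simulated data with the real probes' spread. For 1 line against FGG, 53.7% of the probes changed by 1 on the log2 scale, 98.5% of those changed by 2 and 100% of those changed by 3 were recovered, with 1 false call among the unchanged probes of the 38425. For 1 pair of lines the shares were 46.3%, 95.5% and 98.5%, with 5 false calls, and for the tumour lines against FGG 37.3%, 80.6% and 87.9%, with 3 false calls. Noise was drawn independently for each probe, and FGG was given no deviation of its own. The false calls therefore leave out the dependence of neighbouring probes and, against FGG, the spread of FGG.

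Alternatives covered centring and scaling of the arrays, a filter on noisy probes, other thresholds, robust variance estimation, the slide number as a block, the dye term, each dye orientation alone, averaging within an orientation, leaving out arrays, slides and lines, and arrays as replicates. Values per run, the removal of both arrays that stood apart, and natural logs were added after the data were seen. Alternatives that concern genes and gene lists were not run, for want of gene names.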

Results

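Gene expression was compared between 4 human glioblastoma lines and normal glial cells on 2-colour arrays. A172, T98G, U118 and U87 are established lines derived from human glioblastoma. The labels class A172 and T98G as less aggressive and U118 and U87 as more aggressive. Each line was hybridised together with the same normal glial cells, named FGG, on 4 arrays. The tumour line was in Cy5 on 2 of these arrays and in Cy3 on the other 2, which gave 16 arrays in all. Every array held a log ratio for the same 38425 probes, with 0 values missing.

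The deposited values ran from -8.97 to 7.24. Their log base was not stated. A log10 ratio from a 16-bit scanner cannot exceed 4.82, so the values were read as log2, and every fold below rests on that reading. The direction of the ratio was not stated either. All 16 arrays ran the same way, since the lowest correlation between any pair of them was 0.243. The titles name the Cy5 sample first on every array, the tumour line on 8 arrays and FGG on the other 8, and so do not settle it. Differences are therefore given as positive or negative log ratios and not as higher or lower expression. FGG was 1 control sample present on every array, so a log ratio tested against 0 leaves out the spread of FGG itself. Nothing says that the arrays of a line came from separate cultures, so p-values over arrays measure the spread between hybridisations, which may be technical.

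Arrays of 1 line resembled each other more than arrays of different lines. Over probes, which are not independent replicates, the correlation averaged 0.831 ± 0.115 (SD, n = 8 pairs) for arrays of the same line and dye orientation. It averaged 0.769 ± 0.119 (SD, n = 16 pairs) for the same line in opposite orientations and 0.521 ± 0.114 (SD, n = 96 pairs) for different lines. The share of probes at least 2-fold from 0 was 11.7% ± 3.88 in A172, 12.6% ± 1.59 in T98G, 10.9% ± 0.538 in U118 and 11.7% ± 1.69 in U87 (SD, n = 4 arrays each). A172 replicate 1 stood apart with 17.6% of its probes at least 2-fold from 0 and a mean correlation of 0.559 with the other A172 arrays. U87 replicate 3 had a mean correlation of 0.680 with the other U87 arrays. Without both of these arrays, counts of probes called per line, per pair of lines, over the lines, in 1 line alone, at least 16-fold or in opposite directions moved by less than 1.5 times. Counts of runs were not repeated without them.

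**Figure D1:**
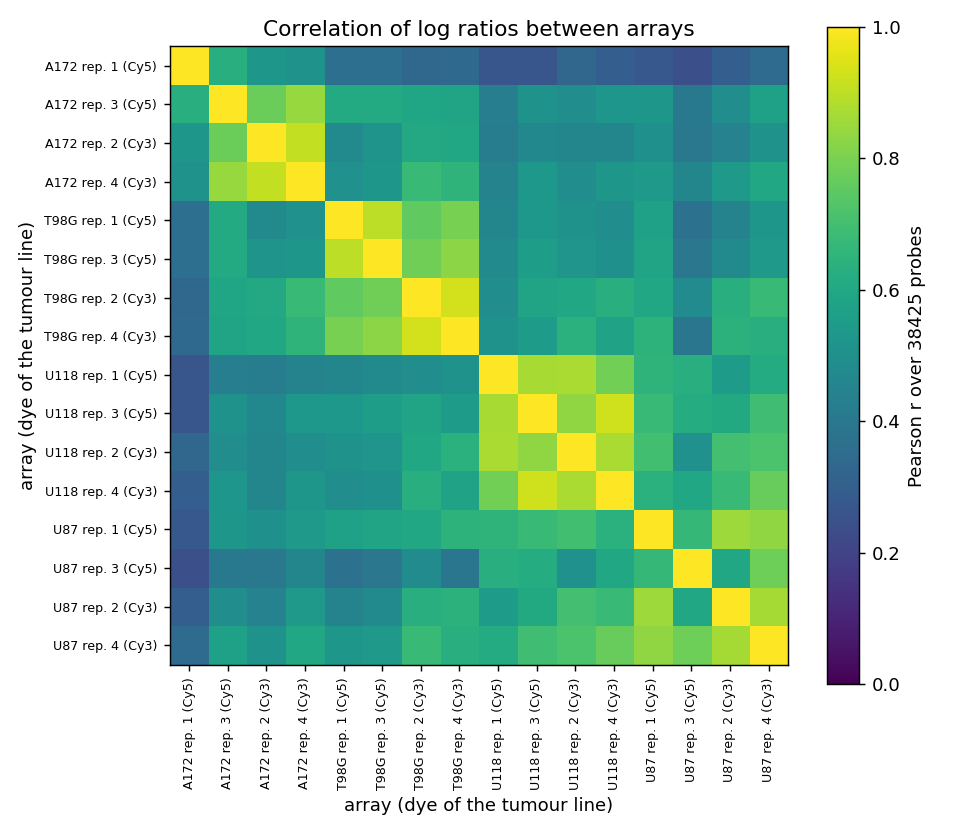
Pearson correlation of the log ratios between each pair of the 16 arrays over 38425 probes, with both axes listing the arrays by line, replicate and dye of the tumour line. Arrays of 1 line form blocks of higher correlation, and A172 replicate 1 has the weakest correlation with its own line, 0.559 on average.

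The probes are known here by their identifiers only, since 0 of the 38425 identifiers were found in the table of human gene names used. Differences are therefore described by probe and by runs of neighbouring identifiers. Probes whose identifiers followed each other closely behaved alike. The correlation of the mean log ratio between 2 successive probes was 0.814 where their identifiers differed by at most 5 and 0.798 for differences over 50 and up to 100. It was 0.0843 for differences over 200 and up to 300 and 0.00252 for differences over 1000. A run was therefore ended wherever 2 successive identifiers differed by more than 200, a limit chosen after the data were seen. This gave 1603 runs with a median of 18 probes and a range of 1 to 210. Within runs neighbours correlated at 0.800, and across the boundaries of runs at 0.00714. Neighbouring probes are thus not independent of each other. Counts of calls against FGG, per pair of lines and over the lines are given below for runs as well. Some other counts of probes stand without a count of runs. What the probes of a run have in common is not known here.

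**Figure D2:**
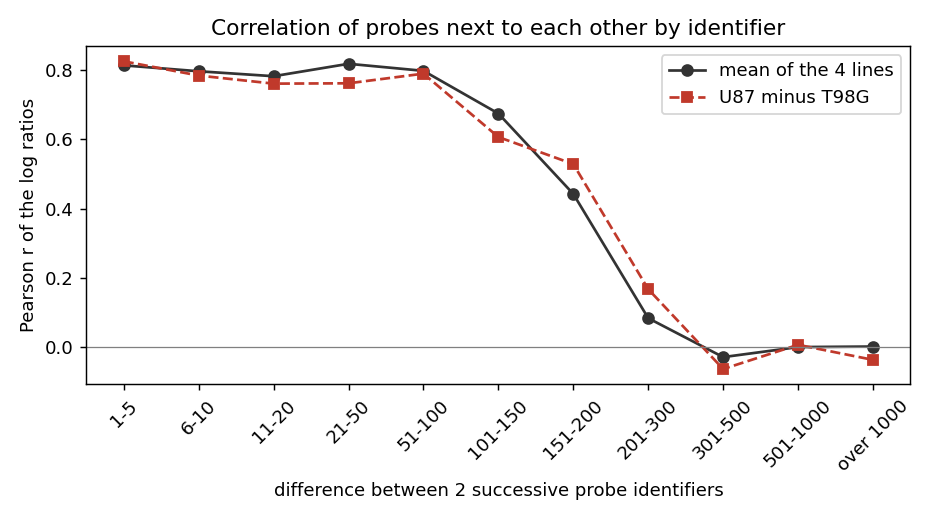
Pearson correlation of the log ratios of 2 successive probes (vertical axis) against the difference between their identifiers (horizontal axis, in classes), for the mean of the 4 lines and for U87 minus T98G. Correlation stays near 0.8 up to a difference of 100 and is near 0 above 300.

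The per-line comparison asked how each tumour line differed from the normal glial cells. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 in limma and a mean change of at least 2-fold. In A172, 1545 probes were positive and 1668 negative, together 3213 or 8.36% of the probes. T98G had 1907 positive and 2218 negative probes, together 4125, the most at the deposited scale; with the arrays scaled to the same spread A172 had more, 4215 against 3789. U118 had 1838 positive and 1821 negative probes, together 3659. U87 had 1681 positive and 1789 negative probes, together 3470. The number of calls on either side was similar within each line at the 2-fold limit, but their size was not. Without the fold limit 61.9%, 59.3%, 58.4% and 55.5% of the calls were positive in A172, T98G, U118 and U87. At least 16-fold changes were found for 101 negative and 12 positive probes in A172 and for 119 negative and 10 positive probes in T98G. U118 had 124 negative and 13 positive probes of that size, and U87 had 69 negative and 11 positive. The median size of the negative calls was 1.64, 1.61, 1.70 and 1.82 on the log2 scale in A172, T98G, U118 and U87, against 1.32, 1.33, 1.27 and 1.35 for the positive calls. With 1 value per run, 33 runs were positive and 48 negative in A172, 38 and 65 in T98G, 39 and 63 in U118, and 40 and 59 in U87. Leaving out the 25% of probes with the largest spread between arrays reduced the counts to 1430 in A172, 1826 in T98G, 1777 in U118 and 1649 in U87.

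**Figure D3:**
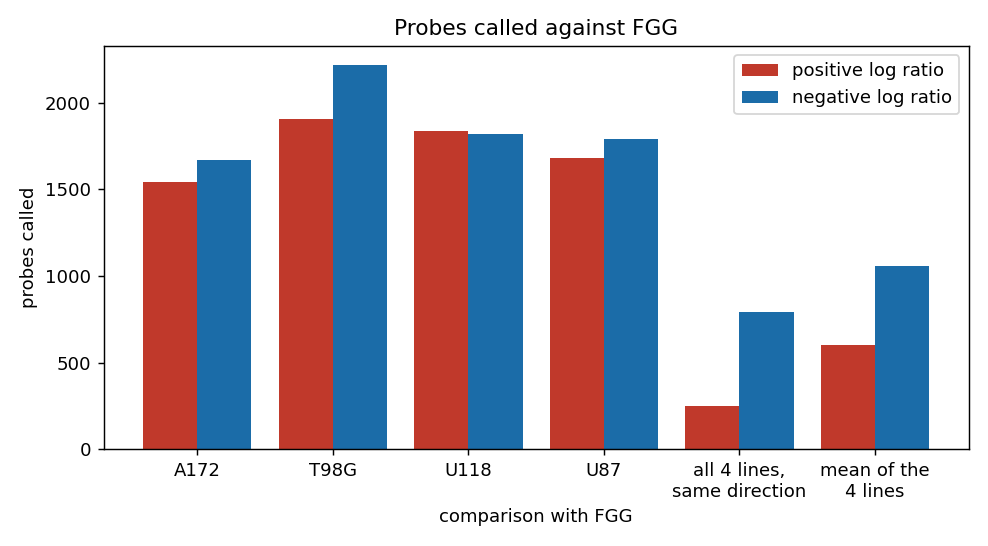
Number of probes called (vertical axis) with a positive or a negative log ratio against FGG in each of the 4 lines, in the same direction in all 4 lines, and for the mean of the 4 lines. Positive and negative bars are of like height in each line, whereas 795 of the probes shared by all 4 lines were negative and 252 positive.

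The next comparison asked which differences from FGG the tumour lines shared. In all 4 lines 252 probes were called positive and 795 negative, together 1047, in 60 and 97 runs. Independent lists of the same lengths would share 0.160 positive and 0.212 negative probes, which leaves out the shared FGG sample. FGG's own deviation is not measured. If it were as large as the spread between the 4 lines, it alone would give 457 positive and 460 negative shared probes, the means of 20 simulations of unchanged lines. The simulated lines had no differences of their own, and their means correlated at 0.880, against 0.511 to 0.751 for the real lines. The simulated numbers are thus not an estimate for these lines. How much of the sharing comes from the single FGG sample is therefore not known. The imbalance also rested on the fold limit, as 1594 positive and 1777 negative probes were shared without it. When 1 tumour line took the place of FGG as the reference, the other 3 lines shared 361 calls against U87, 491 against U118, 612 against A172 and 711 against T98G. With FGG as the reference, any 3 of the lines shared between 1182 and 1342. These counts differ in precision, since a difference between tumour lines carries the spread of both and a test against FGG leaves out FGG's. Fewer calls with a tumour line as the reference can come in part from that. With 1 value per run, 5 runs were positive and 26 negative in all 4 lines.

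With the lines as replicates (n = 4 line means), limma called 604 probes positive and 1060 negative, together 1664. Of these, 524 positive and 1030 negative probes had the same sign on all 16 arrays. With 1 value per run, 13 runs were positive and 39 negative. The count rested on each line to a different degree: it was 482 without U87, 842 without T98G, 924 without U118 and 1150 without A172. At an adjusted p under 0.01 it was 447, and limma's test against a 1.5-fold change (treat) called 534.

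Among runs of at least 3 probes, the strongest shared differences had a negative log ratio. Leading runs were picked after the data were seen, as the 6 highest and 6 lowest means among runs of at least 3 probes that passed the test over the lines. A run of 22 probes had the lowest mean, -3.58 ± 0.398 (SD, n = 4 lines) (limma adjusted p = 0.00366). Its mean was -3.41 in A172, -3.68 in T98G, -4.09 in U118 and -3.16 in U87, and 19 of its probes were called negative in every line. A run of 81 probes had a mean of -2.98 ± 1.14 (SD, n = 4 lines; limma adjusted p = 0.0263), with 74 probes called negative in every line. This run was unequal between lines, at -4.00 in A172, -3.78 in T98G, -2.63 in U87 and -1.53 in U118. A run of 62 probes was weakest in A172, at -1.35, and lay between -3.61 and -3.13 in the other lines. A run of 29 probes averaged -2.82 ± 0.682 (SD, n = 4 lines). The most even of the leading runs held 17 probes and averaged -2.58 ± 0.209 (SD, n = 4 lines; limma adjusted p = 0.00255), and a run of 12 probes averaged -2.46 ± 0.294.

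Among runs of at least 3 probes, the positive ones changed less. The highest mean of these, 1.89 ± 0.942 (SD, n = 4 lines; limma adjusted p = 0.0458), belonged to a run of 4 probes that stood at 0.83 in A172, 1.42 in T98G, 2.41 in U118 and 2.91 in U87. A run of 22 probes averaged 1.60 ± 0.627 and was lowest in A172, at 0.67, against 1.81 to 2.04 in the other lines. Runs of 17, 12 and 24 probes averaged 1.38 ± 0.339, 1.36 ± 0.327 and 1.27 ± 0.231 (SD, n = 4 lines each). The sixth run, of 12 probes, averaged 1.17 ± 0.461. Probes called positive in every line numbered 1 of 4 in the highest run and 3 of 22 in the next. They numbered 13 of 17, 8 of 12 and 16 of 24 in the following runs, and 5 of 12 in the sixth.

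**Figure D4:**
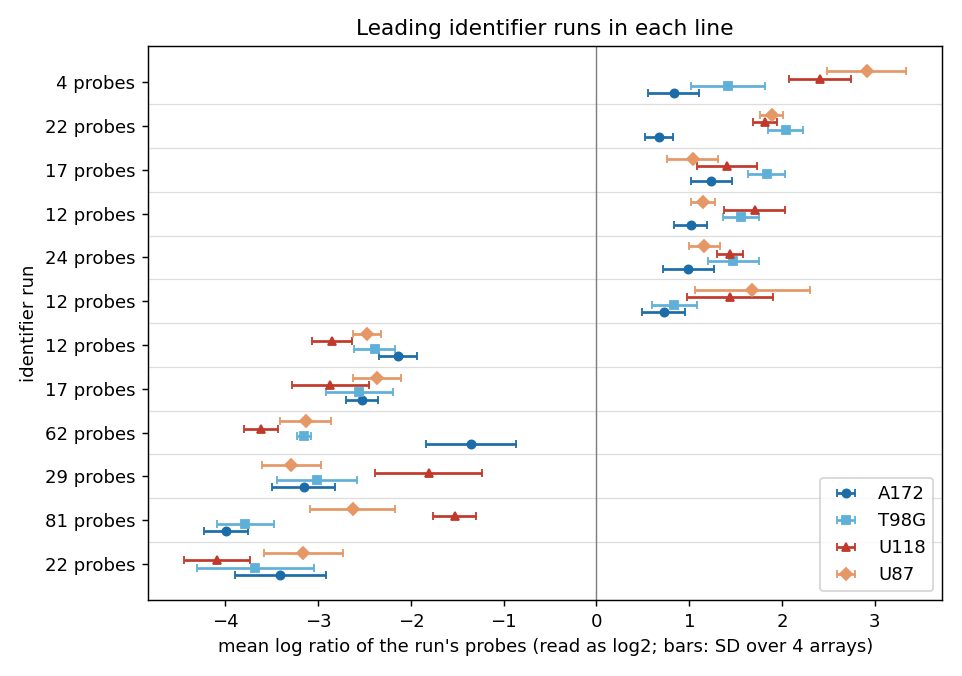
Mean log ratio against FGG (horizontal axis, read as log2) of the 12 leading identifier runs in each line, with points for the means of the 4 arrays and bars for their SD. Among these runs, each of at least 3 probes, the negative ones reach -3.58 on average over the lines and the positive ones 1.89.

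Single probes were named by a rule fixed before the data were examined, as the highest and lowest line averages among called probes with the same sign on all 16 arrays. Probe JHS21942264 had the highest, 3.51 ± 0.926 (SD, n = 4 lines; 11.4-fold; limma adjusted p = 0.0190), with the highest line value, 4.84, in U118 and the lowest, 2.68, in U87. It was alone in its run. Probe JHS21535383 followed at 2.62 ± 0.718 (SD, n = 4 lines; limma adjusted p = 0.0203), with 1.55 in A172 and 2.90 to 3.08 in the other lines, and lay in the positive run of 22 probes. Probe JHS20783960 had the lowest average, -5.45 ± 1.85 (SD, n = 4 lines; 43.9-fold; limma adjusted p = 0.0300). It stood at -2.68 in U118 and between -6.52 and -6.29 in the other lines, and lay in the run of 29 probes. Probe JHS20278393 averaged -5.44 ± 0.649 (SD, n = 4 lines; 43.3-fold; limma adjusted p = 0.00666), from -6.21 in U118 to -4.63 in A172. It lay in the negative run of 12 probes. JHS21942264 and JHS20783960 lost their call without A172, T98G or U87, and JHS21535383 without T98G, U118 or U87, whereas JHS20278393 kept it without any 1 line. Each of the named probes was among the 25% with the largest spread between arrays, which the filter on noisy probes left out.

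The labels also class the lines, which poses the question of what separates the more aggressive lines U118 and U87 from the less aggressive lines A172 and T98G. With lines as replicates (n = 2 per class), limma called 0 probes and 0 runs, and the smallest adjusted p was 0.459 for probes and 0.367 for runs. At an unadjusted p under 0.05 there were 3359 probes, 8.74% of those tested. With the arrays taken as replicates, which leaves out the spread between lines of a class, 1795 probes were called. On simulated data with this design, 0% of the probes changed by 1 on the log2 scale were recovered, 17.9% of those changed by 2 and 39.4% of those changed by 3, so changes of 8-fold were mostly missed.

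Some runs nonetheless separated the classes in size, and their values are given without a call. A run of 37 probes stood at 1.76 in U118 and 1.47 in U87, and at -0.29 in A172 and -0.13 in T98G. A run of 12 probes stood at 2.33 in U118 and 2.19 in U87, and at -0.03 in A172 and 0.58 in T98G. In the opposite direction, a run of 5 probes stood at -1.93 in U118 and -1.67 in U87, and at -0.31 in both A172 and T98G. A run of 30 probes stood at -0.40 in U118 and -0.46 in U87, and at 0.45 in A172 and 0.58 in T98G. The probe of smallest p stood at -4.60 in A172 and -4.68 in T98G and at -0.61 in U118 and -0.44 in U87. At least 2-fold separation, with both lines of 1 class on the same side of both lines of the other, was found for 1510 probes, 864 of them with the more positive log ratio in the more aggressive lines. The other 2 ways of pairing the lines gave 695 and 783 such probes. Lines of either class were separated, at any size, for 41.4% of probes, and those of the other 2 pairings for 28.2% and 30.4%. Each probe separates 1 of these pairings, so at least 1 pairing must reach 33.3%, whatever the classes mean.

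Pairs of tumour lines were compared directly, which removes FGG from the difference. U118 and U87, the lines classed as more aggressive, differed least, with 1769 probes and 46 runs called. The other pairs differed by 2606 to 2927 probes and 67 to 76 runs. A172 and T98G, the lines classed as less aggressive, differed by 2686 probes and 67 runs, close to the pairs that cross the classes. The line means of U118 and U87 correlated at 0.751 over probes, against 0.511 to 0.629 for the other pairs. Part of each correlation comes from the shared FGG sample. The covariance was 0.348 for U118 and U87 and 0.229 to 0.306 for the other pairs, against 0.180 in the simulations of unchanged lines with a deviating FGG. The simulated value follows from the size assumed for FGG's deviation, so it does not measure what FGG adds to these covariances. For U118 and U87 the count of called probes was 715 on the arrays with the tumour lines in Cy5 alone and 1024 on those with Cy3 alone, and for A172 and T98G it was 1525 with Cy5 alone.

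The lines also differed in direction from FGG. For 289 probes, in 66 runs, 1 line was called positive and another negative. Calls confined to 1 line numbered 727 in A172, 1469 in T98G, 985 in U118 and 829 in U87. Such a count does not show that the other lines differ from that line, since a probe can miss the threshold in them narrowly.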

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

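The tests below on A172 replicate 1, U87 replicate 3 and the balance of shared calls were chosen after the results were seen; the splits of arrays were set before they were counted. A single sample far from the others of its set was found in 6 of 92 sets of 4 values, 6.52%, where chance gives about 5%. Some sets overlap, since named probes lie in leading runs.

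A172 replicate 1 lay far from the other A172 arrays in 3 measures. The SD of its log ratios was 0.911 against 0.682 to 0.707, 17.6% of its probes were at least 2-fold from 0 against 9.67% to 9.92%, and its mean correlation with its line was 0.559 against 0.739 to 0.756. RNA of another tumour line is argued against, since differences to the other lines explained 0.391% of the variance of its deviation. A difference at the level of RNA is argued against as the whole cause, because neighbouring probes, which rise and fall together, shared 1.25% of its excess variance. Probe-by-probe measurement error stays open and may account for it: the correlation of its deviations between neighbours was 0.109, against 0.173 to 0.602 on the other 15 arrays. The design gives no group within a line, so no biological cause beyond these was tested.

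U87 replicate 3 was not past the same limit for 1 sample far from the rest, but its deviation from its line had an SD of 0.586 against a median of 0.376 over the other arrays. Measurement error of single probes is argued against as the whole cause, as its deviations correlated at 0.602 between neighbours, above the median of 0.513; but 28.8% of its excess variance was unshared, and its unshared variance was 0.144 against a median of 0.0636, so such error may be part of it. RNA of another of the 4 tumour lines is also argued against as the main source, since differences to those lines explained 7.16% of the deviation. A difference in the RNA of that hybridisation may account for most of it, since neighbours shared 71.2% of its excess variance. The measure cannot tell this from an error that neighbouring probes share, as what they have in common is not known here. Whether culture, extraction or FGG on that array brought the deviation was not tested.

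At the 2-fold limit, calls shared by all 4 lines were 75.9% negative, but without it 1594 were positive and 1777 negative, so the imbalance rested on the limit. Where 0 lies bears on both counts, and no count without the limit was made on centred arrays. A few long runs are argued against as the whole cause of the imbalance, although the 10 fullest held 48.8% of the shared negative probes, since 83.9% of shared calls were negative with 1 value per run. Averaging also drops shared probes whose run mean misses the limit. Runs holding a shared probe numbered 97 on the negative and 60 on the positive side, a smaller imbalance. The number of probes per run may thus be part of the cause. The zero point of the arrays was not decided by any test, as the true zero is unknown: a common shift balances the sides at some size in any case, here 0.3 on the log2 scale, and centring on the medians, within 0.0531 of 0, changes too little. An imbalance of the size that 1 sample can give against 3 others stays open. With A172 as the reference 77.0% of shared calls were negative, above the 70.9% to 74.4% with FGG. With U87, U118 and T98G as the reference the share was 69.8%, 64.6% and 43.7%, each below that range. A property of FGG and one of the tumour lines cannot be separated with 1 FGG sample.

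Some line means lay far from the other lines. Probe JHS21535383 averaged 1.55 in A172 against 2.90 to 3.08 elsewhere. Probe JHS20783960 averaged -2.68 in U118 against -6.52 to -6.29. The positive run of 22 probes, which holds JHS21535383, averaged 0.67 in A172 against 1.81 to 2.04.

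Differences between lines were called for 9 of the 16 named probes and leading runs. These overlap, since JHS21535383, JHS20783960 and JHS20278393 lie in the leading runs of 22 (positive), 29 and 12 (negative) probes. The largest were 3.84 for JHS20783960 and 2.15 for JHS21942264 (both U118 minus U87), -1.53 for JHS21535383 and 1.58 for JHS20278393 (both A172 minus U118). Among runs they were -2.08 for that of 4 probes (A172 minus U87), -1.36 for the positive run of 22 probes (A172 minus T98G), -2.47 and 2.26 for those of 81 and 62 probes (A172 minus U118), and 1.48 for that of 29 probes (U118 minus U87). Opposite calls in different lines concerned 289 probes; a called difference between those lines follows almost by construction from opposite calls in the same fit and is no separate evidence.

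Splits of the 8 arrays of each pair asked whether chance between hybridisations could give the calls between lines. They cannot exclude it, since 1 of 35 splits, 2.86%, is the smallest share possible. Every other split mixes both lines, so a difference between the lines widens its spread and lowers its count. Where the arrays of a line are repeats of 1 extract, the splits do not address the spread between cultures or extracts. In a fit of the 8 arrays of each pair, 1 of the 35 splits, the real one, gave as many calls in each of the 6 pairs. For A172 and T98G the real split gave 2536 calls and the highest other 237. For T98G and U118 these were 2748 and 76, for T98G and U87 2860 and 41, and for U118 and U87 1751 and 46. A172 and U118 gave 2354, A172 and U87 2046, and the highest other split gave 0 in both. Wherever another split gave calls, the highest was the one that follows the dye orientation.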

How the results depend on the processing

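Values per run, the removal of both arrays that stood apart and the natural-log reading were chosen after the data were seen. No named probe changed the sign of its mean under any alternative run. This follows almost by construction, as the named probes are extremes with the same sign on all 16 arrays, and is no separate evidence. Which side held more calls did turn for 7 of the 12 counts with calls: under 7 of 37 alternatives for A172 and U118, 3 for T98G and U87, 6 for A172–U118, 2 for A172–U87 and 1 for U118–U87. Among them, U118 went from 50.2% to 48.0% positive after centring, and A172–U118 from 51.3% to 45.8% without replicate 1. Shared calls and the mean of the lines were mostly negative under every alternative, with at most 47.3% and 46.5% positive. Each count against FGG and each count for a pair of lines had 37 alternatives, and between 30 and 33 of them lay within 1.5 times of the main count; for the mean of the 4 lines this held for 26 of 36. Centring, scaling and robust variance estimation moved no count by more than 1.5 times. Leaving out arrays, slides or lines gave 482 to 1733 for the mean of the lines, with 482 without U87, 842 without T98G, 924 without U118 and 1150 without A172. Fewer lines leave fewer degrees of freedom, but the cause of the unequal loss was not tested. Counts below are in the order A172, T98G, U118 and U87 against FGG, then all lines in the same direction, the mean of the lines, and the pairs A172–T98G, A172–U118, A172–U87, T98G–U118, T98G–U87 and U118–U87. Without the noisiest 25% of probes they were 1430, 1826, 1777, 1649, 454, 776, 1268, 1321, 1252, 1209, 1406 and 923, a larger loss than the share of probes left out; the cause was not tested. With no fold limit they were 10059, 12439, 12207, 12131, 3371, 4501, 5414, 6584, 5668, 6248, 6146 and 4296, which admits smaller changes. With 1 value per run they were 81, 103, 102, 99, 31, 52, 67, 76, 68, 68, 67 and 46 of 1603 runs, which counts other units. Read as natural logs, with a 2-fold limit of 0.693, they were 5317, 6901, 6226, 6096, 1714 and 2603 against FGG, with 34.8% of the shared calls positive, and 4434, 4360, 4429 and 3044 for A172–U118, T98G–U118, T98G–U87 and U118–U87. A test against a 1.5-fold change (treat) gave 534 for the mean of the lines and 1363, 1416, 1423, 1418, 1442 and 668 for the pairs. An adjusted p under 0.01 gave 447 for the mean of the lines. Cy5 alone gave 1525 for A172–T98G and 715 for U118–U87, and Cy3 alone 1024 for U118–U87; these fits use fewer arrays. Arrays as replicates gave 2596 for the mean of the lines and 1795 for the classes, as the spread between lines is then left out. The filter on noisy probes left out all of the named probes, so their calls were not tested under it. Of the named probes, JHS20278393 was called under all 34 alternatives that gave a value for it, with adjusted p up to 0.0468. JHS21942264, JHS21535383 and JHS20783960 each lost the call under 5, among them the 1.5-fold test, the adjusted p under 0.01 and 3 of the 4 leave-one-line-out fits, with adjusted p up to 0.0715, 0.0938 and 0.116. The planned filter on complete values removes nothing, as 0 values were missing, and the planned choices on genes and gene lists were not run. No intensities were used, so the limit that signal over background sets is unknown.

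The slide number, which the lines share, did not pair the arrays. Residuals of arrays with the same number in different lines correlated at -0.134 on average, from -0.450 to 0.462, and 3 of the 16 arrays matched their own number best in another line. With the slide number as a fixed block the counts were 3218, 4122, 3661 and 3469 against FGG, 1045 for all lines in the same direction and 1730 to 2836 for the pairs. As a random block, with a consensus correlation of -0.111, they were 3210, 4128, 3655 and 3465. The block moved no count by more than 1.5 times.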

Other observations

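Some runs of identifiers set 1 line apart from FGG and from each of the other 3 lines, with all 4 limma tests passed in the same direction. This was looked for after the data were seen, among runs of at least 3 probes, and found for 9 runs in A172, 8 in T98G, 8 in U118 and 6 in U87. Each adjusted p below is that of the line's test against FGG, not of its tests against the other lines. In A172 the largest was a run of 5 probes at 2.79 ± 0.133 (SD, n = 4 arrays; limma adjusted p = 1.54e-08), where the other lines lay between -1.23 and -0.54. In T98G it was a run of 12 probes at -2.68 ± 0.125 (SD, n = 4 arrays; limma adjusted p = 2.65e-06), with the other lines between -1.07 and -0.48. In U118 a run of 3 probes stood at -2.68 ± 0.248 (SD, n = 4 arrays; limma adjusted p = 2.42e-11), with the others between -0.77 and 0.08. U87 had the largest of all, a run of 11 probes at 4.02 ± 0.253 (SD, n = 4 arrays; limma adjusted p = 3.35e-10), with the others between -0.31 and 1.99.

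At the 2-fold limit, sharing differed by direction. Of the probes called positive in any line, 3000 were called in 1 line, 868 in 2, 409 in 3 and 252 in all 4. Of the negative ones, 1404 were called in 1 line, 688 in 2, 512 in 3 and 795 in all 4, so more were shared by all lines than by 2 or by 3. Without the limit the shared calls were nearly balanced, 1594 positive and 1777 negative. Calls found in 1 line alone were 600 positive and 127 negative in A172, 831 and 638 in T98G, 680 and 305 in U118, and 636 and 193 in U87. Without A172 replicate 1 and U87 replicate 3 they were 512 and 157 in A172 and 618 and 218 in U87.

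Probes of a run did not always move together. Runs with at least 1 positive and at least 1 negative call numbered 24 in A172, 25 in T98G, 26 in U118 and 18 in U87, between 3.77% and 5.53% of the runs with a call. Runs with 3 or more of both numbered 3, 7, 7 and 6. Within the lowest run, of 22 probes, the line values of single probes ranged from -5.89 to 0.57.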
